A study of Mus musculus with 18 samples.

How the data were processed

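Expression was profiled on 18 mouse arrays, 3 for each of 6 groups: CD1 MEFs, the EOS3F-24 partial iPS line before and after 2i conversion, the EOS3F-28 and EOS3F-29 full iPS lines, and J1 ES cells. Per the labels' protocols, RNA was extracted with the RNeasy Mini Kit and labelled with biotin by a whole-transcript sense target assay. The deposited values are log2 expression values per probe set, made with RMA per the submitters' processing notes, which combines background correction, normalization between arrays and a summary over probes. The RMA version, the genome build and the annotation behind them are not given in the sources used here. The values ran from 0.678 to 13.3, and no pair of arrays correlated above 0.992. RMA compresses differences near background, and its normalization sets the arrays to a like distribution, so a shift common to most genes would be removed.

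The value table holds 34760 probe sets. The platform annotation gave 1 gene symbol for 21640 of them and several for 1321, and 11799 were not listed in it and are unnamed here. Each of 19937 genes was represented by the probe set with the highest mean over all arrays, which mattered for the 954 genes with more than 1. Second probe sets of Kcnma1, Crybg1, Ppia, Eed, Gas5, Baiap2l1 and Dppa3 went the other way in at least 1 comparison that names the gene. Chromosome membership and gene order came from the GRCm38.p6 gene table, and none of its coordinates are used. Chromosome scores use genes with a mean log2 value of at least 6, with 5 and 7 as alternatives.

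Groups and replicate numbers came from the sample titles. A linear model with 1 mean per group was fitted to all 18 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), so that the groups share each gene's spread. The 9 comparisons were tested as contrasts, with the mean of both lines standing for full iPS cells. Genes were called at an adjusted p under 0.05 (Benjamini-Hochberg over all genes) and counted again with at least a 2-fold change. Values are differences of log2 means.

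The lists of 404 genes, of which 368 were measured and 2 of those through an older symbol, the comparisons, the tests and the rule for named genes were fixed before the data were examined. Of 23 lists, 21 were tested with camera at a preset inter-gene correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a comparison; the sex-linked and housekeeping lists served as checks. The other lists cover core, naive and primed pluripotency, fibroblasts and feeder cells, mesenchymal regulators, epithelial, germline, primitive endoderm, trophoblast, mesendoderm, neural, and macrophage and endothelial genes, ERK and Wnt responses, the 2-cell-like state, imprinted genes, heterochromatin and methylation, polycomb, cell cycle, p53 and CDK inhibitors, and glycolysis. Genes are shared by 9 pairs of lists, 2 genes by the primed and heterochromatin lists and 1 by each other pair. Counts "adjusted over the list alone" use Benjamini-Hochberg within the list. Named genes are the 10 largest rises and 10 largest falls per comparison among called genes with at least a 2-fold change and no overlap between arrays of the groups, the 2 largest called rises and falls of each list, and, whether called or not, Pou5f1, Sox2, Klf4, Myc, Nanog, Esrrb, Zfp42, Dppa3, Thy1, Col1a2, Cdh1, Epcam, Dusp6, Axin2, Meg3 and Xist. Symbols of predicted or clone-named genes were left out of the first part. Genes outside this rule that the closing section names were chosen after their values were seen.

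Whether equal replicate numbers pair arrays was checked by correlating their deviations from the group means over genes. Every pair exceeded 0.1 for partial against J1 cells (0.208, 0.242 and 0.223), 2i converted against partial cells (0.383, 0.140 and 0.122), 2i converted against J1 cells (0.563, 0.454 and 0.150) and EOS3F-28 against EOS3F-29 (0.542, 0.639 and 0.149). In these 4 comparisons the numbers were taken to pair the arrays, a pairing that comes from the values and not from the labels. The main model did not use it, and it entered only through the replicate block. Full iPS against J1 cells and converted against full iPS cells reached 0.421 to 0.579 for numbers 1 and 2. They failed only at number 3, at -0.115 to -0.0497, so equal numbers went together there in part.

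For comparisons that share arrays, 100 simulated sets of unchanged groups gave the overlap and correlation expected with no effect. The model was tested on simulated data in which 200 of 19937 genes were changed, in 10 runs. For 2i converted against partial cells it recovered 55.8% of 1.5-fold, 91.6% of 2-fold and 99.1% of 4-fold changes, with 5.47% of calls false. For full iPS against J1 cells it recovered 67.3%, 93.0% and 99.5%, with 4.94% false. Camera, tested for 2i converted against partial cells with lists of 20 genes in 100 runs, called 6% of unshifted lists and 100% of lists shifted by 0.5. The simulated genes varied independently, so these shares do not cover lists whose genes move together. The fibroblast and feeder list, for example, had an estimated correlation of 0.864 for partial cells against MEFs.

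Alternatives fixed beforehand were the mean of a gene's probe sets, testing of all probe sets, leaving out the dimmest 30% of genes, cyclic loess, centring on housekeeping genes, fitting only the arrays compared, a trended robust prior, a replicate block, an adjusted p under 0.01, each full line alone, and leaving out each array. A covariate for the fibroblast list mean on the 15 feeder-grown arrays, and leaving out the replicate 1 arrays of the 5 feeder-grown groups together, were added after seeing the data.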

Results

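Gene expression was measured on 18 mouse arrays in 6 groups of 3 arrays each. The starting cells were fibroblasts from CD1 mouse embryos (MEFs). Retroviruses carrying Oct4, Klf4 and Sox2 had been used to make 3 induced pluripotent stem (iPS) lines from them. EOS3F-24 was described as partially reprogrammed, and EOS3F-28 and EOS3F-29 as fully reprogrammed. The fifth group was EOS3F-24 after conversion in 2i, a MEK inhibitor at 2 μM with a GSK inhibitor at 12 μM, and the sixth was J1, an embryonic stem (ES) cell line. The iPS and ES cells grew on arrested feeder cells with LIF, and the iPS lines were kept in puromycin at 1 μg/mL. The MEFs were not among these feeder-grown groups. In comparisons with MEFs these culture conditions therefore cannot be told apart from reprogramming. All values are log2 array values, differences are on the log2 scale, and errors are SE of the difference unless SD is named. Array medians lay between 3.92 and 4.11, replicate arrays correlated over genes at 0.970 to 0.992, and the number of arrays limits the precision. Nothing in the labels says whether replicates were separate cultures, so the p-values measure only the spread between these arrays, which may be technical.

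How far the partial line had moved from its starting cells was asked first. In EOS3F-24, Pou5f1, which encodes Oct4, stood at 10.96 ± 0.32 against 3.16 ± 0.18 in MEFs (SD, n = 3 each), a difference of 7.79 ± 0.16 (probe set 10444853, adjusted p = 1.03e-15). The array may read viral as well as endogenous transcript for the 3 introduced factors. Other genes of the pluripotency network moved less: Nanog rose by 1.15, Sox2 by 0.96 and Klf4 by 1.20, while Zfp42 was at -0.01 (adjusted p = 0.976) and Dppa3 at 0.31 (adjusted p = 0.336). Esrrb was called at 0.48 (adjusted p = 0.0467), a call lost without any 1 of the 6 arrays: without MEF replicate 1, 2 or 3 its adjusted p was 0.106, 0.125 or 0.0644, and without partial replicate 1, 2 or 3 it was 0.0522, 0.177 or 0.0898. Cyclic loess (0.136), housekeeping centring (0.36), testing of all probe sets (0.0728) and the trended robust fit (0.0509) ended it too.

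The largest rises after Pou5f1 were in Slc38a5, an amino acid transporter (6.89 ± 0.21), the acute-phase gene Saa3 (6.05 ± 0.79), Krtdap, a gene of keratinocyte differentiation (5.73 ± 0.18), the potassium channel gene Kcnma1 (5.28 ± 0.34) and the keratin gene Krt13 (5.23 ± 0.24). Saa3 also averaged higher in converted and J1 cells than in MEFs, so its rise was not particular to the partial line. Srgn, Gcnt3, Stmn2 and Crybg1 rose by 4.60 to 4.77. A second probe set of Kcnma1 was at -0.31 and a second of Crybg1 at -0.08, so these 2 rises rest on 1 probe set each. The largest falls included Adamts5 (-4.18 ± 0.41), Aspn (-4.16 ± 0.49), Ptn (-3.72 ± 0.53), Cnn1 (-3.54 ± 0.25) and Myl9 (-3.49 ± 0.52).

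Of 25 measured fibroblast and feeder genes, 19 fell, 1 rose and 5 were not called, with the same counts adjusted over the list alone; Col5a2 fell by 3.08 and Col1a1 by 3.06 (camera adjusted p = 3.08e-12, adjusted p = 0.4 with an estimated correlation). The member that rose was Dcn at 1.42, which lost its call without MEF replicate 2 (adjusted p = 0.0532) or partial replicate 1 (0.0743). Of 17 mesenchymal regulators 10 fell and 0 rose, or 11 and 0 adjusted over the list alone, led by Tgfb3 (-2.95) and Snai2 (-1.75; camera adjusted p = 1.59e-08, adjusted p = 0.356 with an estimated correlation). Thy1 fell by 1.90 and Col1a2 by 2.85. Of 19 core pluripotency genes 16 rose, 0 fell and 3 were not called, or 17 rose adjusted over the list alone (camera adjusted p = 1.07e-10, adjusted p = 0.0629 with an estimated correlation). Of 17 naive pluripotency genes 7 rose, 2 fell and 8 were not called, or 8 and 2 adjusted over the list alone; Nr0b1 rose by 2.94 (camera adjusted p = 0.0127, adjusted p = 0.462 with an estimated correlation, and 0.0593 with dim genes left out). Of 20 epithelial genes 8 rose and 0 fell, or 9 and 0 adjusted over the list alone, including Krt19 (3.38), Dsp (2.94) and the E-cadherin gene Cdh1 (2.83; camera adjusted p = 0.00458, adjusted p = 0.552 with an estimated correlation). Epcam was at 0.68 (adjusted p = 0.0895), and was called without MEF replicate 2 (0.0129) or partial replicate 1 (0.0183). None of 23 germline genes was called, and their camera adjusted p was 0.851. Imprinted genes went down as a group: 13 of 19 fell and 1 rose, or 15 and 1 adjusted over the list alone, with Igf2 at -2.60 and Mest at -1.88 (camera adjusted p = 2.53e-09, and 0.0325 with an estimated correlation). The noncoding RNA gene Meg3 fell by 1.00. The polycomb, cell cycle, glycolysis and heterochromatin lists were called by camera as well, none of them with an estimated correlation (adjusted p = 0.356 for polycomb and 0.552 for the others). The cell cycle call was lost without MEF replicate 3 (adjusted p = 0.202), and the heterochromatin call without MEF replicate 1 (0.0745) or 3 (0.147) or partial replicate 2 (0.0539) or 3 (0.0701). Cyclic loess (0.0575), housekeeping centring (0.0735), leaving out dim genes (0.146) and fitting only the arrays compared (0.143) ended the heterochromatin call too.

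In total 4717 of 19937 genes were called between partial iPS cells and MEFs, 2722 higher and 1995 lower, and 1241 differed by at least 2-fold, 581 higher and 660 lower. Renormalizing with cyclic loess turned the split to 2138 higher and 2581 lower, and centring on housekeeping genes left 2162 calls.

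Full reprogramming was measured as the mean of EOS3F-28 and EOS3F-29 against MEFs. Tdgf1, a Nodal co-receptor gene, rose by 6.60 ± 0.31, Pou5f1 by 6.43 ± 0.14, Dppa5a by 6.17 ± 0.25 and Utf1 by 5.21 ± 0.14 (adjusted p at most 4.27e-11, n = 6 against 3). Nanog rose by 4.98, Sox2 by 4.45, Esrrb by 3.40, Zfp42 by 3.33 and Dppa3 by 1.45. Each of the 19 core and 17 naive pluripotency genes rose, with the same counts adjusted over each list alone (camera adjusted p = 1.53e-27 and 2.72e-17, and 0.00304 and 0.00737 with an estimated correlation). Of 14 primed epiblast genes 10 rose and 0 fell, with the same counts adjusted over the list alone, including Lefty2 (3.66) and Otx2 (3.19; camera adjusted p = 4.05e-08, and 0.00864 with an estimated correlation).

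Germline genes rose here: 19 of 23 were higher, 1 was lower and 3 were not called, with the same counts adjusted over the list alone, led by Tdrd12 (3.03) and Syce2 (1.87; camera adjusted p = 1.04e-08, adjusted p = 0.128 with an estimated correlation). Of 20 epithelial genes 17 rose and 0 fell, with the same counts adjusted over the list alone, and Epcam rose by 3.95 and Cdh1 by 3.07 (camera adjusted p = 2.97e-10, adjusted p = 0.128 with an estimated correlation). The polycomb list had 13 of 20 members higher and 2 lower, with the same counts adjusted over the list alone; Jarid2 rose by 2.83 and Bmi1 fell by 1.33 (camera adjusted p = 5.46e-05, adjusted p = 0.105 with an estimated correlation). Of 29 heterochromatin and DNA methylation genes 18 rose and 5 fell, with the same counts adjusted over the list alone, including the methyltransferase family genes Dnmt3l (5.01) and Dnmt3b (3.17; camera adjusted p = 5.46e-05, adjusted p = 0.237 with an estimated correlation). Of 25 fibroblast and feeder genes 20 fell and 1 rose, or 21 and 1 adjusted over the list alone (camera adjusted p = 3.2e-10, adjusted p = 0.289 with an estimated correlation). Mesenchymal regulators, imprinted, cell cycle and glycolysis genes were also called as lists, but not with an estimated correlation (adjusted p = 0.153, 0.134, 0.31 and 0.289). Thy1 fell by 1.94 and Col1a2 by 2.73, and Xist, the noncoding RNA of X inactivation, fell by 1.58. The MEF arrays read both Xist (6.70 to 7.13) and Y-linked Eif2s3y (5.80 to 6.11), and the full lines read Eif2s3y at 5.35 to 6.38. A difference in sex between the MEF cultures and the lines thus cannot be told apart from reprogramming in the fall of Xist.

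In total 6968 genes were called between full iPS cells and MEFs, 3417 higher and 3551 lower, and 1558 differed by at least 2-fold, 617 higher and 941 lower. Housekeeping centring left 3883, of which 1282 were higher and 2601 lower. Of the genes changed by at least 2-fold from MEFs, 228 were higher in both partial and full lines and 548 were lower in both, where independent lists would share 17.98 and 31.15 and simulated unchanged groups shared 0. The differences correlated over genes at 0.748, against 0.577 in the simulation, with a covariance of 0.241 against 0.0141. Both comparisons use the same 3 MEF arrays, but the simulation shared them too, so array noise of the size modelled does not account for the excess over it. A deviation common to all 3 MEF arrays would not show in that simulation.

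**Figure D1:**
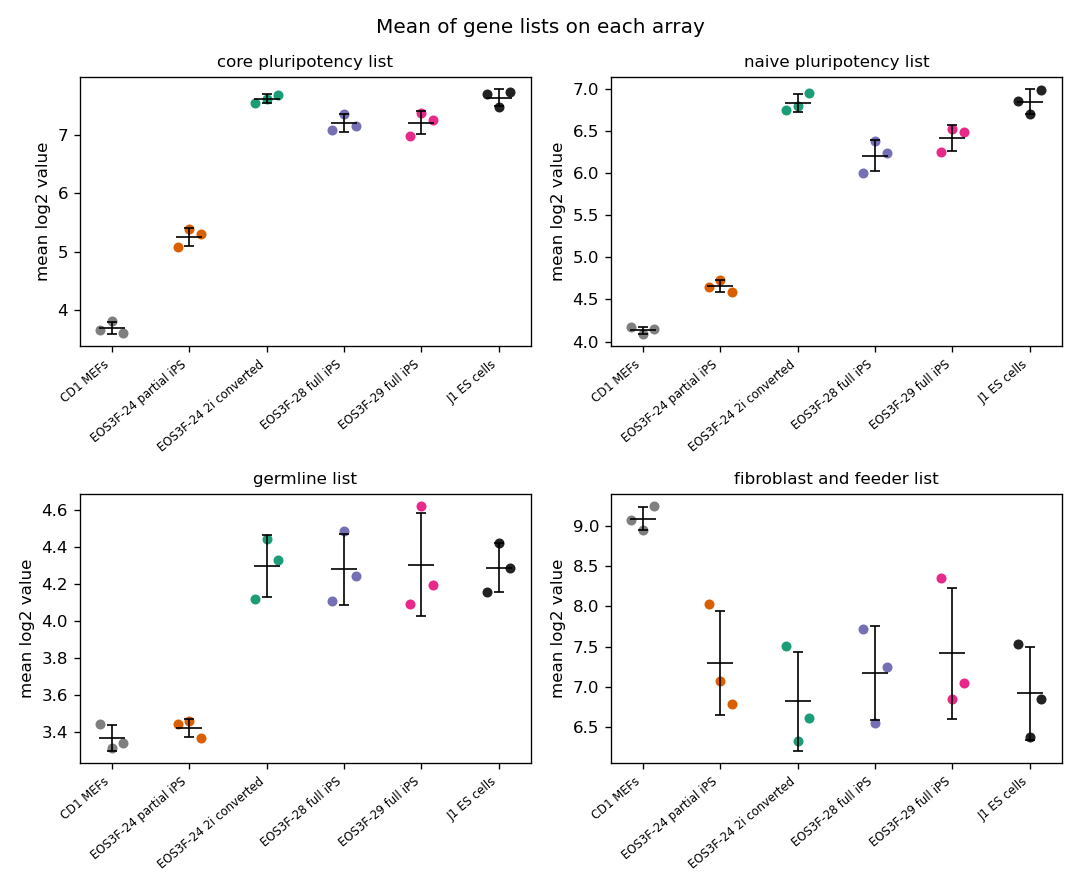
Mean log2 value of 4 gene lists on each array (points) in the 6 groups, with the group mean and SD (bars, n = 3 arrays). The germline list averaged 3.42 in partial iPS cells and 3.37 in MEFs, against 4.28 to 4.30 in the other groups, and the replicate 1 array had the highest fibroblast and feeder mean in each feeder-grown group.

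The partial line was then compared directly with the full lines, the comparison the series is named for. EOS3F-24 had less Nanog (-3.84 ± 0.19), Sox2 (-3.49 ± 0.18), Dppa5a (-4.37 ± 0.25), Utf1 (-4.14 ± 0.14) and Dnmt3l (-4.39 ± 0.16), and also less of the hormone gene Trh (-4.51 ± 0.21) and the glucose transporter gene Slc2a3 (-3.51 ± 0.33; n = 3 against 6, adjusted p at most 5.95e-07). Esrrb was lower by -2.92, Zfp42 by -3.34, Dppa3 by -1.13 and Epcam by -3.27. Pou5f1 went the other way at 1.36, as did Myc at 1.96, and Klf4 was at 0.21 (adjusted p = 0.364). The genes with the largest excess in partial cells included Kcnma1 (6.04 ± 0.29, with its second probe set at -0.06), Srgn (4.20 ± 0.33), Krt13 (3.79 ± 0.20), Cyp2b23 (3.63 ± 0.17) and the epithelial transcription factor gene Ehf (3.47 ± 0.14).

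Of 19 core pluripotency genes 17 were lower and 1 was higher, with the same counts adjusted over the list alone (camera adjusted p = 1.65e-25, and 0.00235 with an estimated correlation). Of 17 naive genes 13 were lower and 0 higher, or 15 and 0 adjusted over the list alone (camera adjusted p = 1.59e-21, and 0.00235 with an estimated correlation). Of 14 primed epiblast genes 8 were lower and 0 higher, or 9 and 0 adjusted over the list alone (camera adjusted p = 1.13e-10, and 0.00235 with an estimated correlation). Of 23 germline genes 15 were lower and 0 higher, or 18 and 1 adjusted over the list alone, with Tdrd12 at -2.94 and Syce2 at -2.45 (camera adjusted p = 9.71e-14, adjusted p = 0.0526 with an estimated correlation). The epithelial list was split. Krt19 (2.81) and Dsp (1.82), of keratin filaments and desmosomes, were higher, while 10 of its 20 members were lower, or 2 higher and 12 lower adjusted over the list alone, among them Epcam and the claudin gene Cldn6 (-2.87; camera adjusted p = 7.49e-07, adjusted p = 0.218 with an estimated correlation). None of the 25 fibroblast and feeder genes was called (camera adjusted p = 0.643), and Thy1 and Col1a2 were at 0.04 and -0.12. Xist was higher by 1.72, and the Y-linked genes Eif2s3y (-1.88) and Uty (-0.87) were lower. Other lists called by camera but not with an estimated correlation were Wnt response (adjusted p = 0.153), imprinted (0.141), heterochromatin (0.355), polycomb (0.175), cell cycle (0.498) and glycolysis (0.596). The glycolysis call was lost without partial replicate 1 (adjusted p = 0.57), EOS3F-28 replicate 2 (0.0707) or EOS3F-29 replicate 2 (0.0822), and with cyclic loess (0.066), the mean of probe sets (0.0686) or EOS3F-29 as the only full line (0.0948). The Wnt response call was lost with EOS3F-28 as the only full line (0.125), and without the replicate 1 arrays of all feeder-grown groups both it (0.0984) and the glycolysis call (0.212) were lost.

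In total 3702 genes were called between partial and full iPS cells, 2549 higher and 1153 lower in partial cells, and 585 differed by at least 2-fold, 329 higher and 256 lower. The split became 1812 and 1614 with cyclic loess. Housekeeping centring left 1737 calls, and leaving out partial replicate 2 left 2380.

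The partial line was also compared with J1 ES cells. Kcnma1 (6.15 ± 0.34, second probe set at -0.17), Slc38a5 (5.82 ± 0.21), Krtdap (5.47 ± 0.18) and Srgn (5.12 ± 0.39) were higher, and Dppa5a (-5.88 ± 0.28), Trh (-5.33 ± 0.24), Nanog (-4.52 ± 0.23), Zfp42 (-4.39 ± 0.22), Sox2 (-4.11 ± 0.20) and Esrrb (-4.03 ± 0.17) were lower (n = 3 each, adjusted p at most 3.56e-08). Myc was higher by 3.01 and Pou5f1 by 1.43. Of 19 core pluripotency genes 17 were lower and 1 was higher, and of 17 naive genes 16 were lower and 0 higher, with the same counts adjusted over each list alone (camera adjusted p = 3.4e-22 and 5.67e-21, and 0.00387 for both with an estimated correlation). Of 14 primed epiblast genes 8 were lower and 0 higher, with the same counts adjusted over the list alone (camera adjusted p = 1.24e-05, and 0.0333 with an estimated correlation). Of 23 cell cycle genes 11 were lower and 1 was higher, or 15 and 1 adjusted over the list alone, with Mybl2 at -1.99 (camera adjusted p = 1.36e-05, adjusted p = 0.392 with an estimated correlation). The fibroblast and feeder list had 0 of 25 members called and a camera adjusted p of 0.128, which became 0.02 with the replicate number as a block. Camera also called the mesenchymal, epithelial, germline, Wnt response, imprinted, heterochromatin, polycomb and glycolysis lists, none of them with an estimated correlation (adjusted p = 0.487, 0.272, 0.206, 0.206, 0.272, 0.472, 0.251 and 0.472). Without J1 replicate 1 the Wnt response (adjusted p = 0.0601) and heterochromatin (0.0662) calls were lost, and without partial replicate 3 the imprinted call (0.0553). The Wnt response call also ended with housekeeping centring (0.0988), and both it (0.11) and the heterochromatin call (0.201) without the replicate 1 arrays of all feeder-grown groups. In total 4571 genes were called, 2647 higher and 1924 lower, and 1093 differed by at least 2-fold. Housekeeping centring left 2170.

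Full iPS lines were next set against J1 cells. Nr1h5, a nuclear receptor gene, was higher in the iPS lines by 2.77 ± 0.21, and Krtdap by 2.26 ± 0.16, while Rps3a1 (-1.84 ± 0.20), H2ax (-1.66 ± 0.14), Fbxo15 (-1.51 ± 0.18) and Dppa5a (-1.50 ± 0.25) were lower (n = 6 against 3, adjusted p at most 0.00158). The Krtdap difference was 3.57 with EOS3F-28 and 0.94 with EOS3F-29 as the only full line, and that of Crybg1 (1.80, with a second probe set at -0.26) was 2.87 and 0.73. Gcnt3 (1.53) and Gda (1.51) were also higher, but were not called with EOS3F-29 as the only full line. Pou5f1 was at 0.06, Klf4 at -0.02, Sox2 at -0.62 (adjusted p = 0.0524) and Nanog at -0.68 (adjusted p = 0.0535), while Esrrb was lower by -1.11 and Zfp42 by -1.05. The Zfp42 call ended with the replicate 1 arrays of all feeder-grown groups left out (adjusted p = 0.0695), and Sox2 and Nanog were called with dim genes left out (adjusted p = 0.0443 and 0.0445), without EOS3F-28 replicate 2 (0.0189 and 0.0297) and without EOS3F-29 replicate 2 (0.031 and 0.0336).

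Of 17 naive pluripotency genes 8 were lower and 0 higher, or 11 lower and 1 higher adjusted over the list alone (camera adjusted p = 8.43e-09, adjusted p = 0.15 with an estimated correlation). Of 19 core genes 6 were lower and 0 higher, or 9 and 1 adjusted over the list alone (camera adjusted p = 2.85e-05, adjusted p = 0.284 with an estimated correlation). The fibroblast and feeder list had 0 of 25 members called, also adjusted over the list alone, with a median of 0.36 (camera adjusted p = 0.00138, adjusted p = 0.819 with an estimated correlation). That call was lost without EOS3F-29 replicate 1 (camera adjusted p = 0.109) or J1 replicate 2 (0.29). With the fibroblast list mean as a covariate, an alternative chosen after seeing the data, it was 0.748. That covariate is the mean of these same genes, so it removes their common difference by construction and was no test of this call. The primed epiblast, mesenchymal, cell cycle and glycolysis lists were called too, but not with an estimated correlation (adjusted p = 0.284 for primed epiblast and 0.819 for the others). Without J1 replicate 2 the primed epiblast (adjusted p = 0.164) and mesenchymal (0.126) calls were lost, and without EOS3F-29 replicate 1 the mesenchymal and glycolysis calls (0.0674 for both). The glycolysis call ended with EOS3F-28 as the only full line (0.0866), and the cell cycle call without the replicate 1 arrays of all feeder-grown groups (0.0756). Genes of chromosome 8, placed by gene order in the GRCm38.p6 assembly, made up 213 of the 691 genes lower in full iPS cells (30.8%), and 4.82% of all genes tested.

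In total 949 genes were called between full iPS and J1 cells, 258 higher and 691 lower, and 80 differed by at least 2-fold. The split was 476 and 555 with cyclic loess and 113 and 168 with housekeeping centring; 520 were called with only the arrays compared, 374 with EOS3F-29 as the only full line, 303 without J1 replicate 3 and 1500 with the fibroblast list covariate.

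The 2i treatment was the next question, asked by comparing converted with untreated EOS3F-24 cells. All converted arrays came from this 1 line, so other changes of the line during conversion cannot be told apart from an effect of 2i. Nanog rose from 4.57 ± 0.51 to 9.17 ± 0.27 and Sox2 from 4.71 ± 0.37 to 8.81 ± 0.06 (SD, n = 3 each), the first a difference of 4.60 ± 0.23 (adjusted p = 1.34e-10 for Nanog and 1.38e-10 for Sox2). Dppa5a rose by 5.58 ± 0.28, Utf1 by 4.49 ± 0.16, Zfp42 by 4.40 ± 0.22, Dnmt3l by 4.25 ± 0.18 and Esrrb by 4.13. The genes that had marked the partial line fell: Krtdap by 5.66, Slc38a5 by 5.62, Kcnma1 by 5.37 (second probe set at 0.12), Krt13 by 5.16 and Srgn by 5.03. Pou5f1 fell by 1.32, Myc by 3.63 and Xist by 2.16, and Klf4 was at -0.21 (adjusted p = 0.428). Col1a2 was at -0.85 (adjusted p = 0.304) and Cdh1 at 0.49 (0.078), and both were called with the replicate block (0.0312 and 0.012).

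Of 19 core pluripotency genes 17 rose and 1 fell, and of 17 naive genes 15 rose and 0 fell, with the same counts adjusted over each list alone (camera adjusted p = 8.64e-23 and 1e-20, and 0.00346 for both with an estimated correlation). Of 14 primed epiblast genes 7 rose and 1 fell, or 8 and 1 adjusted over the list alone, with Lefty2 at 4.36 and Otx2 at 2.68 (camera adjusted p = 4.46e-05, and 0.0482 with an estimated correlation). The list median of 0.39 was -0.03 with housekeeping centring, which moved every gene by the same -0.43, and it stood 0.39 above the median of all genes in both settings. Of 23 germline genes 12 rose and 0 fell, or 13 and 1 adjusted over the list alone, with Syce2 at 3.66 and Tdrd12 at 2.66 (camera adjusted p = 2.08e-08, adjusted p = 0.176 with an estimated correlation). Of 23 cell cycle genes 12 rose and 2 fell, or 13 and 2 adjusted over the list alone, including Mybl2 (2.55) and Ccne1 (1.73; camera adjusted p = 1.06e-05, adjusted p = 0.334 with an estimated correlation). Epithelial genes moved both ways, 9 up and 2 down of 20, or 12 and 2 adjusted over the list alone: Epcam rose by 3.59 and Cldn6 by 2.44, and Krt19 fell by 3.41 and Dsp by 2.35 (camera adjusted p = 0.000103, adjusted p = 0.328 with an estimated correlation). Imprinted genes went up, 7 of 19 with 1 down and the same counts adjusted over the list alone, led by Peg10 (3.94) and Mest (2.47; camera adjusted p = 0.00187, adjusted p = 0.176 with an estimated correlation), with a list median of 0.29 that the same shift put at -0.14. The polycomb list had 9 of 20 members up and 2 down, or 10 and 3 adjusted over the list alone (camera adjusted p = 0.00121, adjusted p = 0.176 with an estimated correlation), and its median of 0.37 was put at -0.06 by that shift. The heterochromatin and DNA methylation list had 8 of 29 members up and 3 down, or 10 and 3 adjusted over the list alone (camera adjusted p = 0.0105, adjusted p = 0.417 with an estimated correlation and 0.113 without the replicate 1 arrays of all feeder-grown groups), and its median of 0.15 was put at -0.27 by that shift. Of 14 glycolysis genes 6 rose and 0 fell, or 8 and 0 adjusted over the list alone (camera adjusted p = 0.000954, adjusted p = 0.417 with an estimated correlation and 0.0611 with cyclic loess); the shift put its median of 0.41 at -0.02.

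Of 20 ERK response genes 5 fell and 1 rose, or 8 and 3 adjusted over the list alone (camera adjusted p = 0.0917, and 0.00731 with housekeeping centring), with Myc and Fos (-1.18) lower, Spry1 higher by 0.66 (not called with that centring), and Dusp6 at 0.46 (adjusted p = 0.229, 0.0186 with the replicate block and 0.00167 with the fibroblast list covariate). Of 14 Wnt response genes 3 rose and 1 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.119); Bmp4 rose by 1.93 and Axin2 was at 0.17. Of 17 mesenchymal regulators 6 fell and 0 rose, with the same counts adjusted over the list alone, among them Tbx15 (-1.63) and Cdh2 (-1.02; camera adjusted p = 0.0157, adjusted p = 0.493 with an estimated correlation). That call was lost without partial replicate 1 (adjusted p = 0.101) or 2i replicate 2 (0.0592) and with the fibroblast list covariate (0.0547). Several other lists were not called: primitive endoderm had 1 of 18 higher and 2 lower (camera adjusted p = 0.886), trophoblast 1 of 14 higher and 4 lower (0.37), mesendoderm 1 of 11 higher (0.606), neural 1 of 14 higher and 5 lower (0.0775, and 0.0241 with housekeeping centring), and macrophage and endothelial genes 0 of 13 higher and 3 lower (0.0917). Adjusted over the list alone the counts were the same apart from mesendoderm, with 0. The fibroblast and feeder list had 0 of 25 called (camera adjusted p = 0.0911, 0.00492 with the replicate block and 0.000398 with housekeeping centring). Of 6 genes of the 2-cell-like state 1 rose (0.0917), and of 13 p53 targets and CDK inhibitors 2 rose and 3 fell (0.37); adjusted over each list alone 1 of the former rose, and 3 of the latter rose and 3 fell.

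In total 4456 genes were called between 2i converted and partial cells, 1866 higher and 2590 lower, and 1041 differed by at least 2-fold, 430 higher and 611 lower. With housekeeping centring 365 were higher and 4500 lower. That centring subtracts the median of 11 measured genes. It moved the median of all genes to -0.43 here, to -0.35 against full iPS cells and to -0.41 against J1 cells. The mean of the 11 genes differed by less than these shifts in all 3 comparisons. It was 9.35 in converted, 9.18 in partial, 9.16 in EOS3F-28, 9.12 in EOS3F-29 and 9.15 in J1 cells. Hprt, an X-linked member of the housekeeping list, was itself higher in converted cells by 1.01, 1.30 and 1.17 in these 3 comparisons, and was not called against partial cells with that centring.

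Of the 585 genes that separated partial from full iPS cells by at least 2-fold, 570 (97.4%) were called in the opposite direction after 2i, 0 in the same direction, and 15 were not called. The count was 246 of the 256 genes lower in partial cells and 324 of the 329 higher. Simulated unchanged groups sharing the partial arrays gave 0.01 on average and 1 at most, and independent lists would give 66.7. The 2 sets of differences correlated over genes at -0.893, against -0.195 in the simulation, with a covariance of -0.187 against -0.0141. Both use the same partial arrays, but the simulation shared them too, so array noise of the size modelled does not account for the excess over it. A deviation common to all of the partial arrays would not show in that simulation. After 2i, 135 of the 585 still differed from full iPS cells, 19 of them on the side where the partial cells had been and 5 of those by at least 2-fold.

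**Figure D2:**
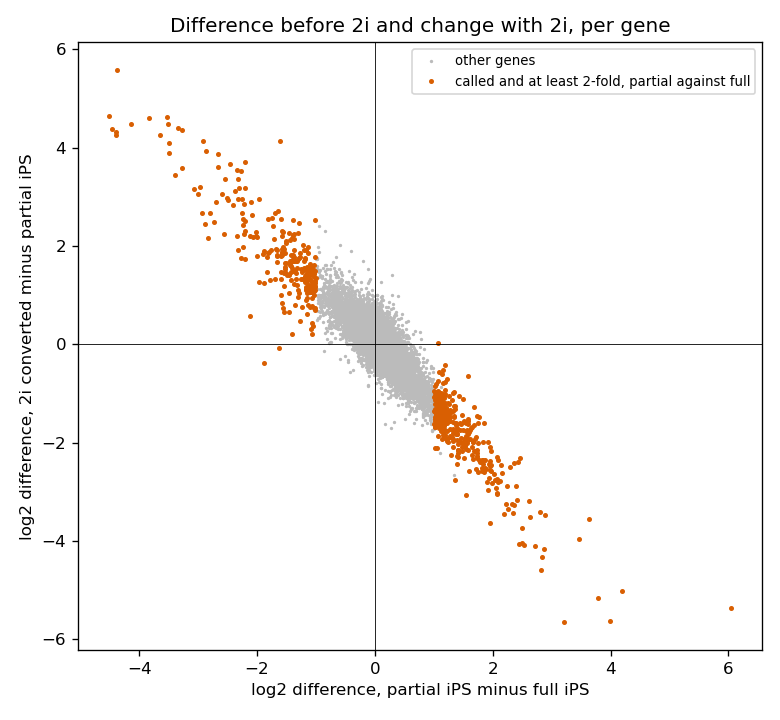
Each point is a gene; the horizontal axis gives partial minus full iPS cells and the vertical axis 2i converted minus partial cells, both as log2 differences. Coloured points are the 585 genes called and at least 2-fold apart between partial and full cells, of which 570 moved the opposite way after 2i.

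What still separated converted cells from the full lines was asked next. Tcl1, a coactivator of Akt, was higher in converted cells by 2.52 ± 0.16, Ooep by 1.52 ± 0.16 and Esrrb and Zfp42 by 1.21 and 1.06. Krtdap (-2.44 ± 0.16), Crybg1 (-1.78 ± 0.12, second probe set at 0.06), St3gal6 (-1.29 ± 0.09) and Eif2s3y (-2.25 ± 0.16) were lower (n = 3 against 6, adjusted p at most 0.00355). Eif2s3y is Y-linked and was already lower by -1.88 in untreated EOS3F-24. With EOS3F-28 as the only full line Krtdap, Crybg1 and St3gal6 were at -3.76, -2.85 and -2.13, and with EOS3F-29 at -1.13, -0.70 and -0.46. Gcnt3 (-1.49) and Krt13 (-1.37) were lower too, but were not called with EOS3F-29 as the only full line. Myc was lower by -1.67, a call lost without 2i replicate 2 (adjusted p = 0.101) or 3 (0.0769) and with EOS3F-29 as the only full line (0.164). Sox2 was at 0.61 (adjusted p = 0.053), and was called without EOS3F-28 replicate 2 (0.0192) or EOS3F-29 replicate 2 (0.0328) and with dim genes left out (0.0438), while Pou5f1 was at 0.05. Of 17 naive pluripotency genes 8 were higher and 0 lower, or 12 and 0 adjusted over the list alone (camera adjusted p = 6.68e-09, adjusted p = 0.145 with an estimated correlation). Of 19 core genes 5 were higher and 0 lower, or 8 and 1 adjusted over the list alone (camera adjusted p = 0.000503, adjusted p = 0.504 with an estimated correlation), with a median of 0.23 that was -0.12 under housekeeping centring, which moved every gene by the same -0.35 here. The fibroblast and feeder list, with 0 of 25 members called and a median of -0.44, was lower (camera adjusted p = 0.000629, adjusted p = 0.687 with an estimated correlation). Its call was lost without 2i replicate 2 (0.0812) or EOS3F-29 replicate 1 (0.0504). The fibroblast list covariate (0.785) removes this list's own mean, so it ended the call by construction and was no test of it.

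Genes of the ERK response were lower as a list against the full lines: 1 of 20 was called lower and 0 higher, or 2 and 0 adjusted over the list alone, with a median of -0.20 (camera adjusted p = 0.0062, adjusted p = 0.504 with an estimated correlation). That call was lost without 2i replicate 3 (adjusted p = 0.06), with EOS3F-28 as the only full line (0.231) and with the fibroblast list covariate (0.0673). Of 14 primed epiblast genes 5 were lower and 1 was higher, with the same counts adjusted over the list alone (camera adjusted p = 0.027, adjusted p = 0.504 with an estimated correlation). It was not called without 2i replicate 3 (adjusted p = 0.055), EOS3F-28 replicate 3 (0.0562) or EOS3F-29 replicate 2 (0.0541) or 3 (0.0875), with EOS3F-29 as the only full line (0.0707), with only the arrays compared (0.057) or with all probe sets tested (0.0541). None of 17 mesenchymal regulators was called, also adjusted over the list alone, and their median was -0.27 (camera adjusted p = 0.0234, adjusted p = 0.687 with an estimated correlation). The list call was lost without 2i replicate 2 (adjusted p = 0.149) or 3 (0.102), EOS3F-28 replicate 1 (0.0846) or EOS3F-29 replicate 1 (0.256), with EOS3F-28 as the only full line (0.161), with all probe sets tested (0.0523) and with the fibroblast list covariate (0.785). Of 23 cell cycle genes 4 were higher and 0 lower, or 9 and 0 adjusted over the list alone (camera adjusted p = 7.57e-05, adjusted p = 0.687 with an estimated correlation), with a median of 0.26 that the common shift of housekeeping centring put at -0.09. Glycolysis had 0 of 14 members called, or 4 higher adjusted over the list alone (camera adjusted p = 0.0062, adjusted p = 0.687 with an estimated correlation), with a median of 0.30 that this shift put at -0.05. It was not called without 2i replicate 2 (adjusted p = 0.132) or EOS3F-29 replicate 1 (0.0594), with cyclic loess (0.439), with EOS3F-28 as the only full line (0.086) or with the fibroblast list covariate (0.169).

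In total 1029 genes were called between converted and full iPS cells, 790 higher and 239 lower, and 73 differed by at least 2-fold. The split was 668 and 483 with cyclic loess and 44 and 862 with housekeeping centring. With EOS3F-29 as the only full line 493 were called, without 2i replicate 2, 351, and without 2i replicate 3, 376. Of the 790 higher genes, 126 lay on chromosome 8, 81 on chromosome 12 and 85 on X, chromosomes that hold 4.82%, 3.27% and 3.72% of the genes tested. Chromosome scores, the median deviation of a chromosome's genes from their means over arrays less that of the other autosomes, were examined after these counts had been seen. The score of converted cells exceeded that of full iPS cells by 0.257 for chromosome 8, 0.284 for chromosome 12 and 0.233 for X, with each of the 3 converted arrays above each of the 6 full arrays. The exact two-sided permutation p was 0.0119 for each, the smallest that 84 splits allow here, and 0.0793 after adjustment over 20 chromosomes. With only 3 chromosomes at that smallest p, the adjusted value could not have passed, so it cannot decide for or against these differences. The next largest score difference was -0.041, for chromosome 10.

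**Figure D3:**
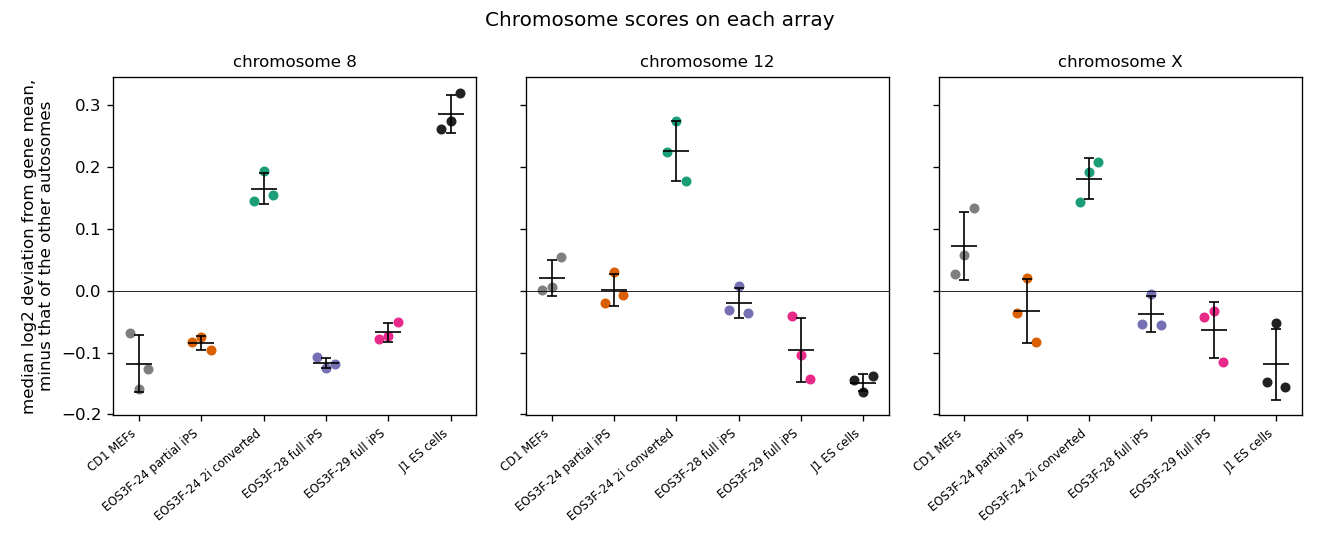
Scores of chromosomes 8, 12 and X on each array (points), in log2 units relative to the other autosomes, with the group mean and SD (bars, n = 3 arrays). Chromosome 8 lay at 0.146 to 0.194 in 2i converted cells and 0.262 to 0.321 in J1 cells, and at -0.125 to -0.0505 in the full iPS lines.

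Converted cells were also set against J1 ES cells. Nr1h5 was higher by 3.79 ± 0.24, the meiotic gene Sycp1 by 1.66 ± 0.13, Galnt6 by 1.52 ± 0.15 and Tcl1 by 1.22, and Eif2s3y (-2.71 ± 0.18), Dnah8 (-1.68 ± 0.19), Rps3a1 (-1.58 ± 0.23) and Uty (-1.39) were lower (n = 3 each, adjusted p at most 0.00157). The Tcl1 call ended with housekeeping centring. Gas5 was higher by 1.58 on its tested probe set and at -0.04 on another, and was not called with the mean of its probe sets (adjusted p = 0.0511). Nanog was at 0.08, Sox2 at -0.01, Esrrb at 0.10, Zfp42 at 0.01 and Pou5f1 at 0.11, none of them called, and Epcam was at 1.03 (adjusted p = 0.0761), and was called with the replicate block (0.0076) and with only the arrays compared (0.0174). Cdh1 was at -0.63 (adjusted p = 0.124), and was called with that block (0.0165). None of the 21 lists was called, the lowest camera adjusted p being 0.608. In total 342 genes were called, 212 higher and 130 lower, and 65 differed by at least 2-fold; 52 of the 212 lay on X and 33 on chromosome 12. The count was 543 with the replicate block, 173 with only the arrays compared, and 155, 136, 223 and 133 without 2i replicate 2, 2i replicate 3, J1 replicate 2 and J1 replicate 3. Housekeeping centring gave 16 higher and 244 lower, and the fibroblast list mean as a covariate gave 831 calls.

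Differences between the 2 full lines were the last comparison. EOS3F-28 had more Krtdap (2.63 ± 0.18), Gcnt3 (2.26 ± 0.18), Tgm3 (2.22 ± 0.31), Crybg1 (2.14 ± 0.14), Slc38a5 (2.13 ± 0.21) and St3gal6 (1.67 ± 0.11), genes of which Krtdap, Gcnt3, Crybg1 and Slc38a5 were among the largest rises in the partial line. Cbln1 (-1.84 ± 0.19), Rnasek (-1.28 ± 0.17) and the X-linked genes Siah1b (-1.21 ± 0.13) and Prps2 (-1.06 ± 0.15) were lower (n = 3 each, adjusted p at most 0.00233); the calls of Tgm3 and Prps2 ended with only the arrays compared. Nanog, Sox2, Esrrb and Zfp42 were at 0.04, -0.17, 0.14 and -0.07. Pou5f1 was higher by 0.90, a call lost without EOS3F-28 replicate 2 (adjusted p = 0.0709) or 3 (0.0655) or EOS3F-29 replicate 1 (0.0537), and with only the arrays compared (0.0648) or housekeeping centring (0.0612). No list was called, the lowest camera adjusted p being 0.0954. In total 106 genes were called, 60 higher and 46 lower, and 41 differed by at least 2-fold. The count was 197 with the replicate block and 46 with only the arrays compared, and 62, 43 and 43 without EOS3F-28 replicate 1, 2 or 3 and 53 and 55 without EOS3F-29 replicate 2 or 3. The split was 94 and 46 with cyclic loess and 58 and 15 with housekeeping centring, and the fibroblast list covariate gave 326 calls.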

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

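The tests on chromosomes 8 and X, on mixed cells and on feeder content were chosen after the results were seen, and the splits of the arrays were planned. The 106 genes called between EOS3F-28 and EOS3F-29 are also the genes whose change from MEFs differed between these lines, and the 3702 called between partial and full lines stand in the same relation. Outside the genes analysed, 903 of 13120 probe sets with no single gene symbol were called between 2i converted and partial cells, 359 higher and 544 lower.

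For comparisons with 84 splits of the arrays into groups of the same sizes, 1 split, the real one, called as many genes. It called 6105 for full iPS cells against MEFs (highest other 30), 3128 for partial against full iPS cells (90), 368 for full iPS against J1 cells (81) and 608 for converted against full iPS cells (145), each fitted on the arrays compared as 2 groups, with both full lines in 1 group. Every other split mixes arrays of different lines, which widens the spread and lowers the count. Arrays of 1 line may be technical repeats, so these splits cannot exclude a chance difference between single lines. The comparisons of 3 arrays against 3 have 10 splits, too few for a share under 0.05. Their real values were 4782 for partial cells against MEFs, 4532 against J1, 4860 for converted against partial cells, 173 for converted against J1 cells and 46 for EOS3F-28 against EOS3F-29, with 0 as the highest other in each; for the 4 paired ones that also holds among the 4 splits that part as many pairs.

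Chromosome 8 genes were higher in converted than in full iPS cells by a score difference of 0.257, in 3 of 3 converted arrays. The exact two-sided permutation p was 0.0119, the smallest possible, and 0.0793 adjusted, a value that could not have passed with so few arrays. Strain variants under the probes would be the same before and after 2i, but the score rose within EOS3F-24 by 0.25, from between -0.096 and -0.0746 to between 0.146 and 0.194, which argues against them if the converted cells are that line as labelled (3 arrays against 3 allow no exact permutation p under 0.1). Medians in 4 equal parts of the chromosome by gene order were 0.285, 0.217, 0.366 and 0.312 against full iPS cells, with 81.1% to 85.2% of genes higher. Against untreated EOS3F-24, the same line, they were less even, at 0.1065, 0.259, 0.373 and 0.246, with 57.4% to 69.8% higher. Extra copies of the whole chromosome in converted cells could give medians above 0 in all parts, a hypothesis with no direct measure of copy number. For J1 against full iPS cells the difference was 0.378, with medians of 0.359, 0.394, 0.427 and 0.431 in the same 4 parts, so this pattern was not particular to converted cells. There strain and line cannot be told apart because they split the arrays the same way. Regulation of these genes by 2i was not tested.

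X genes were higher in converted than in full iPS cells, with medians of 0.518, 0.333, 0.140 and -0.136 in 4 equal parts by gene order. Against EOS3F-28 alone they were 0.535, 0.228, 0.0496 and -0.00548, and against untreated EOS3F-24, the same line, 0.353, 0.241, 0.0638 and 0.196. In the last part EOS3F-29 arrays scored 0.078 to 0.163 and converted arrays -0.0536 to 0.04, so its sign depends on the line compared. Reactivation of a whole second X may therefore remain, since the lowest part against untreated cells was at 0.0638 with arrays of both groups overlapping, and a few strongly changed genes may too, since 66.9% of all scored X genes were higher than in full iPS cells, between the bounds set for and against that. Xist averaged 7.05 in untreated EOS3F-24, 4.88 in converted cells, 5.21 in EOS3F-28 and 5.44 in EOS3F-29. Y-linked Eif2s3y read 3.375 to 4.27 on the untreated and converted EOS3F-24 arrays, and 5.35 to 6.49 on the full iPS and J1 arrays. Uty read 3.29 to 3.93 and 4.11 to 5.02, while Kdm5d overlapped between them. In comparisons of EOS3F-24 with those lines, a sex-chromosome difference between lines thus cannot be told apart from reprogramming state or 2i.

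Of 20 genes at least 3 log2 units higher in partial cells than in MEFs, J1 cells and EOS3F-29, 15 were called higher in EOS3F-28 than in EOS3F-29. The rule held EOS3F-29 low and set no bound on EOS3F-28, so it tilts this count towards EOS3F-28. Partial cells mixed into the EOS3F-28 cultures could raise such genes there, at a median share of 15.4%, with single shares from -1.58% to 33.4%. That median was fitted to the same 20 genes, so closeness to it is partly built in and cannot decide. Of the genes, 85% lay within 1 log2 unit of the level the median share predicts, between the bounds set for and against mixing. Kcnma1 (-3.29), Cyp2b23 (-1.63) and Srgn (-1.60) lay below the predicted level. The tables argue against more feeder cells: in 100% of those 15 genes every EOS3F-28 array lay above every MEF and EOS3F-29 array (Crybg1 averaged 3.49 in MEFs and 6.34 in EOS3F-28), which no mixture of EOS3F-29-like cells with feeder cells like these MEFs would give. A difference between the lines themselves was not tested.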

How the results depend on the processing

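The covariate for the fibroblast list and the joint omission of replicate 1 arrays were tests chosen after the data were seen; all other alternatives were planned. Each of 71 called list results and 625 named gene results was repeated under many settings, and the counts here are of these repeats. Directions of called lists by camera reversed in 0 cases. A list call was kept in 1253 repeats and lost in 122, and 58 of these losses came with an estimated correlation. Among named genes 587 repeats lost a call, 71 gained one and 10593 left it unchanged, with 323 of the losses coming with 1 array left out. Housekeeping centring moved every gene by -0.43 between converted and partial cells, which put 2 genes with small called rises just below 0 and uncalled, Eomes at -0.11 (adjusted p = 0.72) and Sesn1 at -0.0014 (0.996). Unless stated here the cause was not tested; a stricter threshold calls fewer genes by construction, and the array signal near background limits what dim genes can show.

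In the order partial against MEFs, full against MEFs, partial against full, partial against J1, full against J1, converted against partial, converted against full, converted against J1 and EOS3F-28 against EOS3F-29, at least 2-fold changes numbered 1241, 1558, 585, 1093, 80, 1041, 73, 65 and 41. An adjusted p under 0.01 left 3052, 2294, 2903, 345, 2891, 405, 125 and 36 in that order, full against MEFs staying within 1.5 times. Housekeeping centring left 2162, 3883, 1737, 2170 and 281 in the first 5. Only the arrays compared gave 520 for full against J1, 173 for converted against J1 and 46 for the full lines. EOS3F-29 as the only full line gave 374 against J1 and 493 for converted cells. The replicate block gave 1596 for full against J1 and 1572 for converted against full, which are not paired, and 543 for converted against J1 and 197 for the full lines, which are. In comparisons that are not paired the block added calls of Epcam and the primitive endoderm list (adjusted p = 0.0456) for partial against MEFs, Dusp6 for full against MEFs and for partial against full, Sox2, Myc, Nanog, Epcam and Xist for full against J1, and Sox2 and Col1a2 for converted against full; beyond these and the paired values given with their results it changed no other call of a named gene or list. The fibroblast covariate gave 1500, 831 and 326 for full against J1, converted against J1 and the full lines.

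With 1 array left out the counts ran from 3461 to 4483, 5800 to 7296, 2380 to 4402, 3378 to 4589, 303 to 1180, 3208 to 4456, 351 to 1166, 133 to 391 and 43 to 102, in the same order. Genes called in the opposite direction after 2i ran from 525 of 541 separating genes to 660 of 678, against the 570 of 585 reported. Without the replicate 1 arrays the counts were 5077, 7577, 4037, 4577, 671, 4408, 1081, 420 and 101, and 785 of 806 separating genes were called in the opposite direction after 2i. In that setting 34 calls of named genes and 6 of lists were lost, and 8 of named genes gained; the lists are named with their comparisons.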

Other observations

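None of these values was planned as a test. Chromosome 12 scores were higher in converted than in full iPS cells by 0.284 (exact two-sided permutation p = 0.0119, adjusted 0.0793). Medians in 4 equal parts by gene order were 0.219, 0.195, 0.389 and 0.259 against full iPS cells. Against untreated EOS3F-24 they were 0.295, 0.116, 0.342 and 0.292. Chromosome 12 genes made up 33 of the 212 genes higher in converted than in J1 cells. X genes made up 52 of those 212 and 15 of the 106 genes called between the full lines, 11 of them among the 46 lower in EOS3F-28. The fibroblast and feeder list was highest in the replicate 1 array of each of the 5 feeder-grown groups. Saa3 averaged 3.75 ± 0.94 in MEFs, 9.80 ± 0.05 in partial cells, 7.44 ± 1.20 in converted cells and 7.20 ± 1.27 in J1 cells (SD, n = 3 each).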
